A study of Bos taurus with 9 samples.

How the data were processed

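Total RNA from pooled bovine oocytes and embryos was sequenced on an Illumina instrument. Per the labels' protocols, cDNA was made with SuperScript III, tailed with poly(A), amplified with Ex Taq HS, fragmented by ultrasound and made into libraries with a NEBNext Ultra DNA kit. Amplification from few cells adds noise for genes with few molecules. The protocols do not describe a strand-marking step, so reads from a gene and an overlapping antisense partner cannot be told apart, and genes with near-identical copies are uncertain.

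The authors deposited 1 table of FPKM values, with 24616 Ensembl gene identifiers in rows and 9 libraries in columns, each column named as its sample. The unit comes from the file's name, and the values do not contradict it. Per the submitters' processing notes, bcl2fastq 2.16, HISAT 0.1.6, StringTie 1.0.4, Bowtie2 2.2.5, RSEM 1.2.12 and the genome build UMD3.1 were used. The notes give no roles or order, and which of these tools made the deposited FPKM values is not given in the sources used here. FPKM divides fragments by transcript length and by the library's fragments, so it does not show a change in the total amount of RNA per oocyte or embryo, and a rise in abundant genes lowers all others. Read counts were not used here, and no count model was fitted.

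FPKM keeps no read totals, but a low gene's values step by the worth of 1 read. The ratio of the smallest steps between each pair of libraries gave relative depths of 80.1%, 93.8% and 99.1% of the deepest library for MII replicates 1, 2 and 3, 97.3%, 96.9% and 96.7% for the IVF replicates, and 99.1%, 95.5% and 100% for the SCNT replicates. These steps are approximate, since between 24.5% and 40.6% of the genes used for a pair lay within 0.03 of the common log2 ratio. The values were not taken back to whole reads, the absolute depth is unknown, and no counting interval is given. Some values of 0 may be failed estimates: 55 genes were above 20 FPKM in at least 1 library and at 0 in another, 4 of them above 1000 FPKM. These were counted over all 9 libraries whatever their group, so the count cannot tell failed estimates from differences between groups. A gene at 0 is therefore said only to be listed at 0, its libraries' values are given singly, and no fold is given against a group at 0.

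Samples were grouped by their titles into MII oocytes, IVF 2-cell embryos and SCNT 2-cell embryos, with 3 libraries each. The comparisons were SCNT minus IVF, IVF minus MII and SCNT minus MII. Genes with at least 1 FPKM in at least 3 of the 9 libraries were tested (9458 genes). Values were taken as log2(FPKM + 1), and limma 3.58.1 in R 4.3.3 fitted all 9 libraries with a term per group, 1 shared estimate of the spread and a mean-variance trend, with Benjamini-Hochberg adjustment within each comparison and a threshold of 0.05. A log2 change is on the log2(FPKM + 1) scale, which understates the change of low genes. Library measures were compared by two-sided exact permutation tests, whose smallest p for 3 against 3 libraries is 0.1. Simulations, principal components and figures used R 4.3.3, Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.

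The limma fit was tested on simulated data with 100 genes changed by 1 and 100 genes changed by 2 on the log2 scale among 9458. For SCNT minus IVF it recovered 86% and 98% of them and called 10 unchanged genes. For IVF minus MII it recovered 83% and 99% with 6 unchanged genes called, and for SCNT minus MII 82% and 99% with 6. The simulated noise was drawn independently for each gene, and only genes with a mean above 1 on the log2 scale were changed. The simulation holds no deviation that many genes of a library share, so its recovery and false calls may not carry over to the real libraries.

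The design, the alternatives and the rule for named genes were fixed before the data were examined. The rule took the largest log2 changes in each direction among genes with an adjusted p under 0.05, a gene symbol, no overlap between the libraries of the groups compared and a mean of at least 5 FPKM in the higher group, together with members of 30 fixed gene lists and a short list of genes to be given whatever their values. The deposited table does not pair identifiers with names, and 0 of 24616 identifiers matched the bovine reference gene table used here (assembly ARS-UCD2.0, whose Ensembl column is empty). The rule was therefore applied without the symbol, and the first 2 identifiers per direction and comparison are given. The gene lists, their set tests and the fixed genes were not analysed here, and no function, position or annotation is given for any gene. Abundance classes by mean FPKM over the 9 libraries, with borders at 5, 100 and 1000 FPKM, were chosen after the data had been seen.

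Alternatives were pseudocounts of 0.1 and 5, no filter on low values, a filter of 5 FPKM, FPKM rescaled to a sum of 1000000 per library, median-ratio scaling over genes with a mean of at least 10 FPKM, quantile normalization, a fit of only the 2 groups compared, the replicate number as a block, no mean-variance trend, robust eBayes, a minimum log2 change of 1, counting genes from 0.1 or 5 FPKM, and leaving out each library in turn. Alternatives added after seeing the data were the FPKM total as a covariate, an adjusted p under 0.1, and quantile normalization with only 2 groups fitted. No library was left out of the main results.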

Results

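RNA was sequenced from pools of bovine (Bos taurus, Holstein) oocytes and embryos in 3 groups. MII oocytes are mature, unfertilised eggs arrested at metaphase of the second meiotic division. IVF embryos come from eggs fertilised by sperm in culture, and SCNT embryos come from eggs whose own nucleus was replaced by that of a somatic cell. Both kinds of embryo were collected at the 2-cell stage, when the embryo still relies mainly on RNA stored in the egg. Each group had 3 libraries. An MII library came from a pool of 3 oocytes and an embryo library from a pool of 6 embryos, so the stage and the pool size changed together in each comparison with oocytes. The question named for the series was how gene expression differs between IVF and SCNT embryos.

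Expression was given as FPKM (fragments per kilobase of transcript, scaled to the library's fragments) for 24616 bovine gene identifiers. The FPKM values of a library summed to between 1153912 and 1386979. Read totals were not used here, but the steps between low FPKM values gave the relative depth of the libraries, which lay between 80.1% (MII oocyte replicate 1) and 100% (SCNT replicate 3) of the deepest. The identifiers are not paired with gene names in the files, and none of them matched a name in the reference table used here, so genes are described by number, abundance and direction, with at most 2 identifiers per direction and comparison. The labels do not say whether the pools of a group came from separate animals or cultures, so all p-values measure the spread between these libraries only, part of which may be technical.

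More genes reached 1 FPKM in the 2-cell embryo libraries than in the oocyte libraries, which came from smaller pools. At 1 FPKM or more, MII oocytes had 8128 ± 224 genes (SD, n = 3), IVF embryos 9353 ± 114 (SD, n = 3) and SCNT embryos 8995 ± 283 (SD, n = 3). IVF embryos exceeded oocytes by 1225 genes and SCNT embryos exceeded them by 867 genes. Every embryo library lay above every oocyte library, and both differences had a two-sided exact permutation p of 0.1, the smallest that 3 against 3 libraries can give (adjusted p = 0.15 over the 3 comparisons). At this cut-off SCNT and IVF embryos overlapped, with a difference of -358 genes and a two-sided exact permutation p of 0.2. The difference was -213 without SCNT replicate 1 and -496 without SCNT replicate 2, and -203 when genes were counted from 0.1 FPKM. Counted from 5 FPKM, SCNT embryos had 5961 ± 224 genes (SD, n = 3) and IVF embryos 6388 ± 113 (SD, n = 3). There the libraries did not overlap, with at most 6174 genes in SCNT and at least 6295 in IVF libraries, so the separation depended on the cut-off. The 10 most abundant genes took a similar share of the FPKM total in MII oocytes (26.2% ± 0.784, SD, n = 3), IVF embryos (26.1% ± 0.337, SD, n = 3) and SCNT embryos (26.3% ± 0.24, SD, n = 3).

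Oocytes stood apart from both kinds of embryo. Across the 9458 genes with at least 1 FPKM in at least 3 libraries, the correlation of log2(FPKM + 1) between libraries of 1 group ran from 0.978 to 0.989, and between IVF and SCNT libraries from 0.975 to 0.982. It was 0.931 to 0.958 between MII and IVF libraries and 0.907 to 0.952 between MII and SCNT libraries. These are correlations across genes, which are not independent replicates. The first principal component held 62.9% of the variance and separated oocytes from embryos. The second held 13.7% and separated SCNT from IVF embryos, but MII replicate 2, at -22.3, lay on the side of the IVF libraries and the other MII libraries, at 11.1 and 9.44, on the side of the SCNT libraries.

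**Figure D1:**
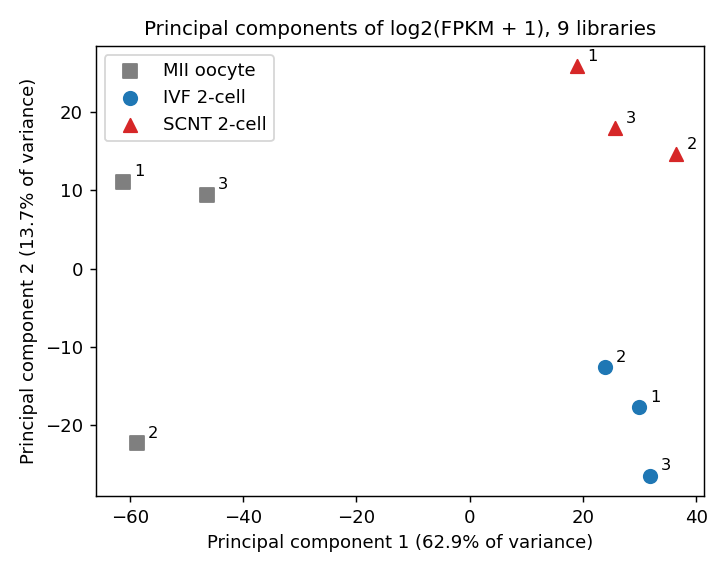
Scores of the 9 libraries on the first and the second principal component of log2(FPKM + 1), in units of the score, with each point 1 library and its replicate number beside it. Oocytes (grey squares) lie at the left and embryos at the right, and SCNT libraries (red triangles, 14.6 to 25.8 on the second component) lie above IVF libraries (blue circles, -26.4 to -12.6).

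SCNT and IVF embryos at the 2-cell stage differed in few genes past the threshold, and some of these differed by a large amount. With limma on log2(FPKM + 1), 17 of 9458 genes had an adjusted p under 0.05, 11 of them higher and 6 lower in SCNT embryos. At an adjusted p under 0.1, a setting added after seeing the data, limma called 1429 genes, 157 higher and 1272 lower. The low count at 0.05 therefore does not show that the embryos were alike. ENSBTAG00000012370 was at 45.7, 36.7 and 43.6 FPKM in SCNT replicates 1, 2 and 3, against 0, 2.23 and 0.474 FPKM in the IVF replicates and 0.662, 0.467 and 5.4 FPKM in the oocytes (log2 change 4.67, SE 0.532, adjusted p = 0.00445, limma). ENSBTAG00000042662 was at 23, 25.8 and 23.6 FPKM in the SCNT replicates and was listed at 0 in every IVF and every MII library (adjusted p = 3.73e-08, limma). The libraries at 0 add no spread to the shared estimate, so this p may be far too small. The gene also passed the filter only through the SCNT libraries. In the other direction, ENSBTAG00000007296 was at 15.2, 8.4 and 10 FPKM in the IVF replicates, against 0, 2.19 and 1.9 FPKM in the SCNT replicates, and was listed at 0 in all MII libraries (log2 change -2.50, SE 0.382, adjusted p = 0.0307, limma). ENSBTAG00000000271 had 42.8 ± 6.2 FPKM (SD, n = 3) in SCNT embryos, 79.1 ± 4.99 FPKM (SD, n = 3) in IVF embryos and 76.5 ± 9.81 FPKM (SD, n = 3) in oocytes (log2 change -0.88, SE 0.143, adjusted p = 0.0436, limma).

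Set against the oocyte, these 17 genes fell into several patterns. Of the 11 genes higher in SCNT than in IVF embryos, 8 were also higher in SCNT embryos than in MII oocytes, while IVF embryos and oocytes were not called apart. A further 2 were above the oocyte level in SCNT embryos and below it in IVF embryos, and 1 was below the oocyte level in both, less so in SCNT embryos. Of the 6 genes lower in SCNT than in IVF embryos, 3 were above the oocyte level in both kinds of embryo and 2 were above it in IVF embryos, with SCNT embryos and oocytes not called apart. The remaining 1, ENSBTAG00000000271, was below the oocyte level in SCNT embryos, with IVF embryos and oocytes not called apart. The median log2 change was 1.37 among the 11 higher genes and -1.14 among the 6 lower genes, and 12 of the 17 (9 higher and 3 lower) changed by at least 1 on the log2 scale.

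**Figure D2:**
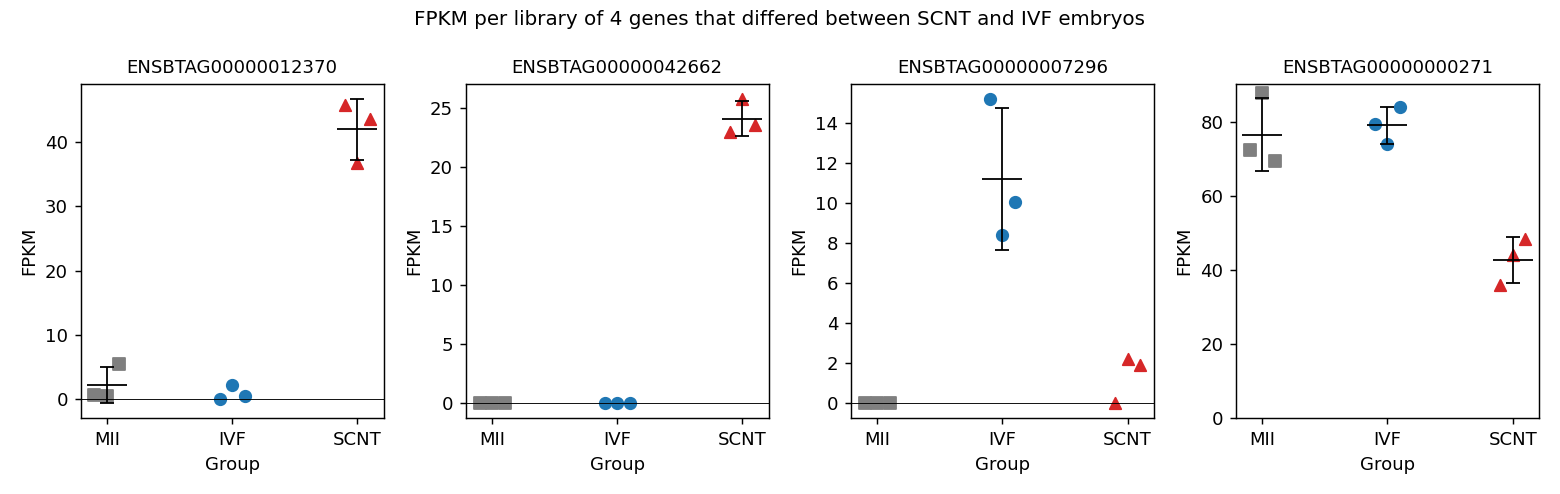
FPKM (linear vertical axes) of ENSBTAG00000012370, ENSBTAG00000042662, ENSBTAG00000007296 and ENSBTAG00000000271 in MII oocytes, IVF embryos and SCNT embryos, with each point 1 library, and the mean and SD (n = 3) drawn in black for groups in which no library is listed at 0. SCNT libraries lie between 36.7 and 45.7 FPKM for ENSBTAG00000012370 and between 36.1 and 48.3 FPKM for ENSBTAG00000000271, outside the range of the IVF libraries in both.

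Beside these genes, SCNT libraries lay a little below IVF libraries across most of the transcriptome. The median log2 change of all 9458 genes was -0.25, and 3913 genes (41.4%, where chance gives 10% on average) had no overlap between the 3 SCNT and the 3 IVF libraries, 3475 of them lower and 438 higher in SCNT embryos. Genes of a library can move together, so by chance alone the share in 1 grouping can lie far from 10%. The shift depended on the scaling, at -0.31 for FPKM rescaled to a common total, -0.05 with median-ratio scaling and -0.03 with quantile normalization. Median-ratio scaling sets the libraries level at the median of genes with a mean of at least 10 FPKM, and quantile normalization makes their distributions equal. Small values are thus built into both, and they cannot tell whether the shift is real. With quantile normalization, 2387 genes (25.2%) had no overlap, 1363 lower and 1024 higher. Abundant genes went the other way. Per library, the median of the 183 genes with a mean of 1000 FPKM or more was 0.20 higher on the log2 scale in SCNT embryos (pooled SD 0.0242, n = 3), or 0.45 higher relative to the median of all genes. The 4745 genes of 5 to 100 FPKM were 0.30 lower (change -0.30, pooled SD 0.0665, n = 3), or -0.06 relative to that median, and the 3430 genes under 5 FPKM changed by -0.22 (pooled SD 0.0954, n = 3). This last value depended on the pseudocount and the filter, at -0.32 with a pseudocount of 0.1, -0.09 with a pseudocount of 5 and -0.07 without a filter on low values. The 1100 genes of 100 to 1000 FPKM changed by -0.08 (pooled SD 0.027, n = 3). In each of these 4 classes the SCNT and IVF libraries did not overlap, with a two-sided exact permutation p of 0.1, the smallest possible (adjusted p = 0.133 over 12 comparisons of classes). These directions hold for FPKM as deposited and for FPKM rescaled to a common total, where the sizes differ (0.11 in the class of 1000 FPKM or more, and -0.18 in that of 100 to 1000 FPKM). With median-ratio scaling the changes, from the lowest class to the highest, were -0.06 (libraries overlapping, two-sided exact permutation p = 0.4, n = 3), -0.08, 0.16 and 0.45, so the class of 100 to 1000 FPKM turned. With quantile normalization, which makes the distributions of the libraries equal, they were -0.01, -0.05, -0.06 and -0.02. There the libraries overlapped in the lowest class (two-sided exact permutation p = 0.5, n = 3) and in the class of 1000 FPKM or more (two-sided exact permutation p = 0.6, n = 3). The difference in the class of 1000 FPKM or more was thus lost.

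The number of genes called between SCNT and IVF embryos was unstable. It was 1265 (141 higher and 1124 lower) when only these 6 libraries were fitted. It was 25 (22 higher and 3 lower) with median-ratio scaling and 65 (53 higher and 12 lower) with quantile normalization. It was 5 with the FPKM total of the library as a covariate, a setting added after seeing the data. The FPKM totals of SCNT libraries (1276123 to 1294594) and IVF libraries (1197565 to 1206014) did not overlap. This covariate therefore stands in part for the group, and the fall to 5 is no evidence about the genes. With 1 library left out, the number of genes called was 0 without SCNT replicate 3 (2156 genes at an unadjusted p under 0.05 in limma). It was 6 without IVF replicate 3 and 8 without SCNT replicate 2. It was 11 without IVF replicate 1, 12 without IVF replicate 2 and 12 without MII replicate 1. It was 27 without MII replicate 3, 36 without SCNT replicate 1 and 1618 without MII replicate 2. With all libraries, 2856 of 9458 genes had an unadjusted p under 0.05 in limma, above the share of 0.05 that unchanged genes with independent noise would give. A shift or deviation that many genes of a library share could also raise this number. It therefore does not show how many genes changed. The call of ENSBTAG00000012370 was lost in 2 of 18 alternative settings (adjusted p from 0.000237 to 0.0716), that of ENSBTAG00000007296 in 8 of 18 (0.00615 to 0.151) and that of ENSBTAG00000000271 in 12 of 18 (0.0137 to 0.22), while ENSBTAG00000042662 passed in each of the 15 settings that tested it. The log2 change of ENSBTAG00000012370 ran from 3.01 to 6.36 and that of ENSBTAG00000007296 from -3.83 to -1.35, with these ends set by the pseudocounts. That of ENSBTAG00000000271 stayed between -0.97 and -0.64.

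**Figure D3:**
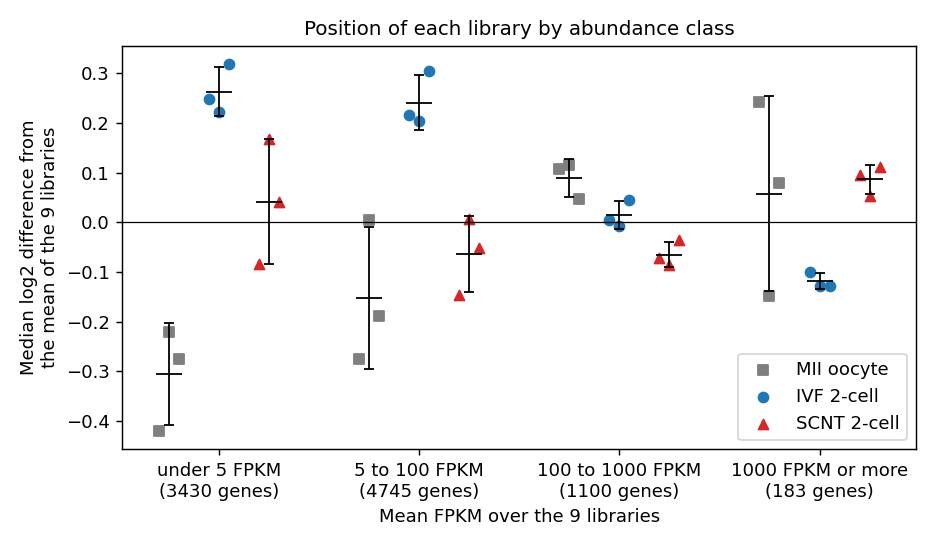
Median log2 difference of each library from the mean of the 9 libraries (vertical axis, log2 of FPKM + 1), for 4 classes of genes by mean FPKM, with each point 1 library and the mean and SD (n = 3) in black. SCNT libraries (red triangles) lie below IVF libraries (blue circles) in the 3 lower classes and above them in the class of 1000 FPKM or more, where the MII libraries (grey squares) run from -0.15 to 0.24; quantile normalization leaves -0.02 there and median-ratio scaling turns the class of 100 to 1000 FPKM.

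From MII oocyte to IVF embryo, the levels of many genes changed, most of them upwards for FPKM as deposited. Limma gave 5108 genes at an adjusted p under 0.05, 4212 higher and 896 lower in IVF embryos, and 2120 of them (1850 higher and 270 lower) changed by at least 1 on the log2 scale. ENSBTAG00000046547 was at 27.5, 20.5 and 43.2 FPKM in the IVF replicates, against 0, 0 and 3.16 FPKM in the oocytes (log2 change 4.22, SE 0.509, adjusted p = 6.65e-05, limma). ENSBTAG00000032453 was at 23, 31.7 and 31.5 FPKM in the IVF replicates, against 0, 1.57 and 1.54 FPKM in the oocytes (log2 change 3.98, SE 0.34, adjusted p = 7.98e-06, limma). ENSBTAG00000014772 fell from 192 ± 39.4 FPKM (SD, n = 3) in oocytes to 15.3 ± 7.48 FPKM (SD, n = 3) in IVF embryos (log2 change -3.64, SE 0.292, adjusted p = 5.6e-06, limma). ENSBTAG00000001415 fell from 62.6 ± 11.3 FPKM (SD, n = 3) to 5.34 ± 1.24 FPKM (SD, n = 3), with a log2 change of -3.33 (SE 0.208, adjusted p = 1.96e-06, limma).

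For FPKM as deposited, the balance of higher and lower genes was not the same in each abundance class. Among the 3430 genes under 5 FPKM, 1698 were higher and 81 lower in IVF embryos than in oocytes, and among the 4745 genes of 5 to 100 FPKM, 2195 were higher and 407 lower. Among the 1100 genes of 100 to 1000 FPKM, 287 were higher and 342 lower, and among the 183 genes of 1000 FPKM or more, 32 were higher and 66 lower. Per library, the medians of the classes under 5 and of 5 to 100 FPKM were 0.57 and 0.39 higher in IVF embryos on the log2 scale, but changed by -0.06 and -0.04 with quantile normalization, and the class of 5 to 100 FPKM was 0.17 higher with median-ratio scaling. The class of 100 to 1000 FPKM changed by -0.08 as deposited, -0.31 with median-ratio scaling, -0.0036 with quantile normalization and -0.00019 for FPKM rescaled to a common total. In the class of 1000 FPKM or more the IVF and oocyte libraries overlapped, with a change of -0.18 (two-sided exact permutation p = 0.4, n = 3) that was -0.08 without MII replicate 1, -0.28 without MII replicate 2, -0.10 for FPKM rescaled to a common total, -0.42 with median-ratio scaling and -0.01 with quantile normalization. The class under 5 FPKM was 0.15 higher without a filter on low values, 0.86 with a filter of 5 FPKM, 0.87 with a pseudocount of 0.1 and 0.23 with a pseudocount of 5. The median log2 change of all genes was 0.40 for FPKM as deposited and 0.44 for FPKM rescaled to a common total. It was 0.21 with median-ratio scaling and -0.05 with quantile normalization. Relative to the median as deposited, ENSBTAG00000046547 changed by 3.82 and ENSBTAG00000014772 by -4.05 on the log2 scale. The share of higher genes depended on the scaling, at 82.5% of 5108 calls for FPKM as deposited, 86.2% of 5000 for FPKM rescaled to a common total, 67.7% of 4803 with median-ratio scaling and 47.9% of 4166 with quantile normalization (1995 higher and 2171 lower).

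From MII oocyte to SCNT embryo, the levels of many genes changed as well. Limma gave 4906 genes at an adjusted p under 0.05, 3193 higher and 1713 lower in SCNT embryos, and 1906 of them (1470 higher and 436 lower) changed by at least 1 on the log2 scale. ENSBTAG00000042662, listed at 0 in all oocyte and IVF libraries, was among the higher genes. ENSBTAG00000031758 rose from 6.51 ± 7.25 FPKM (SD, n = 3) in oocytes to 122 ± 17.9 FPKM (SD, n = 3) in SCNT embryos (log2 change 4.52, SE 0.584, adjusted p = 0.000121, limma), with 63 ± 24 FPKM (SD, n = 3) in IVF embryos. ENSBTAG00000014772 fell here too, to 10.6 ± 2.77 FPKM (SD, n = 3), with a log2 change of -4.07 (SE 0.292, adjusted p = 3.39e-06, limma). ENSBTAG00000047645 passed the test in the lower direction (log2 change -6.27, SE 1.54, adjusted p = 0.00597, limma). Over 18 alternatives its adjusted p in limma was at most 0.0255. The change rests on 2 SCNT libraries listed at 0, which may be failed estimates. Without SCNT replicate 2 all SCNT libraries are listed at 0 and add no spread. No change is given for that setting, and its p may be too small. ENSBTAG00000047645 was at 975, 226 and 266 FPKM in the oocytes, 343, 508 and 1723 FPKM in the IVF replicates and 0, 129 and 0 FPKM in the SCNT replicates.

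For FPKM as deposited, genes under 5 FPKM again rose more often than they fell in SCNT embryos, with 1283 higher and 217 lower than in oocytes, and those of 5 to 100 FPKM had 1570 higher and 1010 lower. Among genes of 100 to 1000 FPKM, 283 were higher and 441 lower, and among those of 1000 FPKM or more, 57 were higher and 45 lower. Per library, the median of the class under 5 FPKM was 0.35 higher in SCNT embryos than in oocytes, but changed by -0.07 with quantile normalization. It was 0.09 higher without a filter on low values, 0.60 with a filter of 5 FPKM, 0.55 with a pseudocount of 0.1 and 0.13 with a pseudocount of 5. In the class of 5 to 100 FPKM the SCNT and oocyte libraries overlapped, with a change of 0.09 (two-sided exact permutation p = 0.4, n = 3) that was 0.03 without MII replicate 1, 0.17 without MII replicate 2 and -0.09 with quantile normalization. The class of 100 to 1000 FPKM changed by -0.15 as deposited and by -0.06 with quantile normalization. In the class of 1000 FPKM or more the libraries overlapped as well, with a change of 0.03 (two-sided exact permutation p = 0.8, n = 3) that was 0.14 without MII replicate 1, -0.06 without MII replicate 2, 0.0069 for FPKM rescaled to a common total and -0.02 with quantile normalization. The median log2 change of all genes was 0.16 for FPKM as deposited and 0.13 for FPKM rescaled to a common total. It was 0.17 with median-ratio scaling and -0.08 with quantile normalization. Relative to the median as deposited, ENSBTAG00000031758 changed by 4.36 and ENSBTAG00000014772 by -4.23 on the log2 scale. The share of higher genes was 65.1% of 4906 calls for FPKM as deposited, 65.3% of 4388 for FPKM rescaled to a common total, 63.7% of 5191 with median-ratio scaling and 44.3% of 5072 with quantile normalization (2249 higher and 2823 lower).

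**Figure D4:**
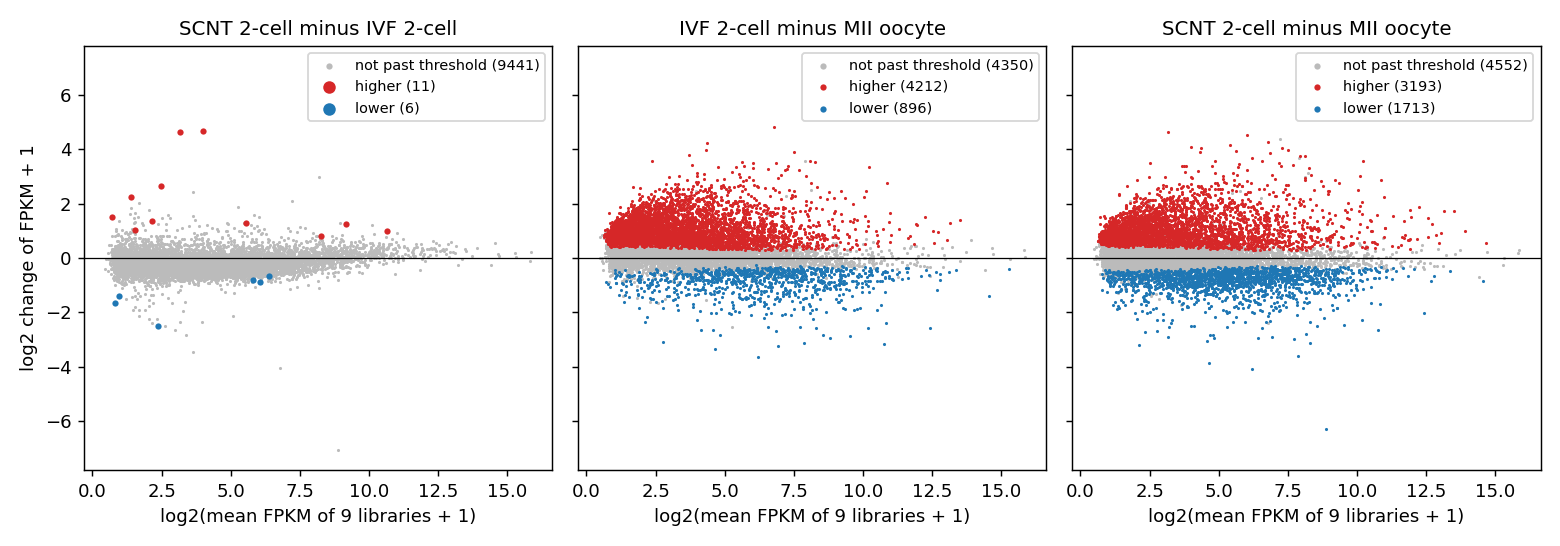
Log2 change of FPKM + 1 (vertical axis) against log2 of the mean FPKM of the 9 libraries + 1 (horizontal axis) for 9458 genes in each comparison, with each point 1 gene and the number of genes in each colour in the legend. Genes with an adjusted p under 0.05 in limma are red where higher and blue where lower in the first group named, 17 between SCNT and IVF embryos, 5108 between IVF embryos and oocytes and 4906 between SCNT embryos and oocytes; with quantile normalization the lower genes outnumber the higher ones in both comparisons with oocytes.

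IVF and SCNT embryos shared many of their differences from the oocyte. Of the genes higher than in oocytes, 2932 were called in both kinds of embryo, where independent lists of these sizes would share 1422, and of the lower genes 788 were called in both, where independent lists would share 162. The shared genes made up 69.6% of the higher and 87.9% of the lower genes of IVF embryos, and 91.8% of the higher and 46% of the lower genes of SCNT embryos, shares that depend on the lengths of the lists (896 genes were lower in IVF and 1713 in SCNT embryos). A call in 1 kind of embryo alone does not show that the embryos differed in that gene. The log2 changes of IVF and SCNT embryos against oocytes had a Pearson correlation of 0.902 across 9458 genes, against 0.501 on average in 100 simulations of unchanged groups compared with shared controls. Their covariance was 0.59, against 0.0266 in the simulations, a difference of 0.564, and 81.3% of genes changed with the same sign, against 66.6%. With 3 oocyte libraries the controls could not be split into parts of at least 2 libraries each, so part of the excess in overlap may come from the shared controls.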

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

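Of the tests in this part, the counts of other splits were planned, and the tests of the abundance pattern were chosen after that pattern had been seen.

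The change from the oocyte differed between SCNT and IVF embryos in the genes named here, as tested by the SCNT minus IVF comparison itself in limma with all 9 libraries. ENSBTAG00000012370 was higher in SCNT embryos by 4.67 on the log2 scale and ENSBTAG00000042662 was at 24.1 FPKM on average in SCNT embryos and listed at 0 in IVF embryos. ENSBTAG00000007296 differed by -2.50 and ENSBTAG00000000271 by -0.88 on the log2 scale. The call was lost in 2 of 18 alternative settings for ENSBTAG00000012370 (adjusted p up to 0.0716), in 8 of 18 for ENSBTAG00000007296 (up to 0.151) and in 12 of 18 for ENSBTAG00000000271 (up to 0.22), and in none of the 15 that tested ENSBTAG00000042662. For ENSBTAG00000042662 the libraries listed at 0 add no spread, so its p may be too small. Among the 17 genes called, 2 were above the oocyte level in SCNT embryos and below it in IVF embryos. Groups of 3 libraries were not tested for outlying libraries.

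The 6 libraries of each comparison can be split into 3 and 3 in 10 ways, too few for a share under 0.05. In each comparison 1 of the 10 splits, the real one, gave as many genes. The highest count of any other split was 1 gene against 17 for SCNT and IVF embryos, 2 against 5108 for IVF embryos and oocytes, and 1 against 4906 for SCNT embryos and oocytes. Every other split mixed libraries of both groups, so a difference between the groups entered its spread and lowered its count. The distance between the counts therefore does not measure how far they lie beyond chance, and no conclusion is drawn from it.

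In SCNT embryos, genes of 1000 FPKM or more were higher and genes of 5 to 100 FPKM lower than in IVF embryos, so the gap between these classes differed by 0.509 on the log2 scale (0.0292 with quantile normalization, which makes the distributions equal). A common scaling factor per library is argued against, since it leaves the gap in place and the gap differed by 6.22 pooled SDs. A difference in depth is argued against too, since the mean log2 relative depth of SCNT and IVF libraries differed by 0.0179. A library property that also varies between replicates remains a candidate explanation, since the gap had a range of 0.671 over the MII libraries, 1.32 times the SCNT minus IVF difference, although it was 0.115 over the IVF and 0.194 over the SCNT libraries. A biological difference between SCNT and IVF embryos stays open, untested.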

How the results depend on the processing

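The FPKM total as a covariate, an adjusted p under 0.1, quantile normalization with 2 groups fitted, and all settings of the abundance classes were tests chosen after the result was seen. The counts of genes against oocytes stayed within 1.5 times under every setting except a minimum log2 change of 1, which by its construction left 2120 genes for IVF and 1906 for SCNT embryos. The genes called were less stable than their counts. With quantile normalization, 2751 of the 5108 genes of IVF minus MII were called again (4166 called). In SCNT minus MII, 3840 of the 4906 were called again (5072 called). With median-ratio scaling these numbers were 4147 (4803 called) and 4829 (5191 called). Leaving out 1 library gave 4233 to 5364 genes for IVF and 4033 to 4696 for SCNT embryos. The FPKM totals of SCNT and IVF libraries did not overlap, so the total as a covariate stands in part for the group. The SCNT minus IVF count of 17 fell to 7 with a pseudocount of 0.1, to 11 without the mean-variance trend and to 5 with the FPKM total as a covariate. It rose to 35 with a pseudocount of 5, 34 with robust eBayes, 65 with quantile normalization, 1265 with only the 2 groups compared, 121 with quantile normalization and only these groups, and 1429 (157 higher and 1272 lower) at an adjusted p under 0.1. All 17 genes were among those called in each of these settings with a larger count, but only 14 of them with median-ratio scaling (25 called) and 11 without SCNT replicate 1 (36 called). Settings with a similar or smaller count exchanged genes too. Of the 17, only 6 were called without IVF replicate 2 (12 called), 10 without a filter on low values (15 called) and 7 without IVF replicate 1 (11 called). Leaving out 1 library gave 0 to 1618 genes: 0 without SCNT replicate 3 (limma; 2156 at an unadjusted p under 0.05), 6 without IVF replicate 3, 8 without SCNT replicate 2, 11 without IVF replicate 1, 27 without MII replicate 3, 36 without SCNT replicate 1 and 1618 without MII replicate 2. The median SD across genes was 0.24 in MII, 0.16 in IVF and 0.185 in SCNT libraries, but leaving out MII replicates 1 and 3 gave 12 and 27 genes, and the cause of these moves was not tested. The correlation of the changes against oocytes, 0.902, was 0.877 without a filter on low values, where more low genes enter, and 0.886 to 0.917 with 1 library left out.

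Of 210 values of printed genes under alternatives, 188 kept direction and passed the threshold, 22 kept direction only, all in SCNT minus IVF, and 0 reversed. Of 192 values of the 12 class medians, 33 moved by more than 1 SD and 8 had the other sign, 6 of these with quantile normalization, 1 with median-ratio scaling (genes of 100 to 1000 FPKM, SCNT minus IVF, 0.16) and 1 without MII replicate 2 (genes of 1000 FPKM or more, SCNT minus MII, -0.06). Leaving out an SCNT library removed ENSBTAG00000042662 through the filter, so these settings gave it no value. Unknown absolute depth limits what can be said of low genes and of genes listed at 0. The alternatives for the gene lists and the fixed genes, including estimated correlation and fry, were not run, since no identifier matched a name.

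With the replicate number as a block, 9 genes were called in SCNT minus IVF, 4933 in IVF minus MII and 4714 in SCNT minus MII. The numbers are shared only as numbers: the deviations of same-numbered libraries correlated between -0.167 and -0.000782, and 0 of 9 libraries correlated best with its own number.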

Other observations

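In this part, the counts of genes on and off and the tests of the excess of higher genes were chosen after the results had been seen, and the tests of incomplete change were planned before theirs.

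Many genes were at 1 FPKM or more in all libraries of one group and under 1 FPKM in all libraries of another. Of the genes tested, 7258 were at 1 FPKM or more in all 9 libraries. In both kinds of embryo, 335 genes were on while off in oocytes, against 4 genes on in oocytes and off in both kinds of embryo. IVF embryos had 553 genes on that were off in oocytes, and SCNT embryos 406. Oocytes had 7 genes on that were off in IVF embryos and 47 that were off in SCNT embryos. Between embryos, 63 genes were on in IVF and off in SCNT libraries, and 11 were on in SCNT and off in IVF libraries. On and off mean only the side of 1 FPKM on which the libraries lay. In SCNT minus IVF, limma called only 6 genes lower and 11 higher, so most of the 63 genes were not called. The counts are for FPKM as deposited and were not repeated under other scalings. Against oocytes, the median of genes under 5 FPKM was 0.57 higher in IVF and 0.35 higher in SCNT embryos. With quantile normalization it changed by -0.06 and -0.07.

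The hypothesis that SCNT embryos fall short of the IVF level in genes that change after the oocyte stage, beyond the shift of other genes, was tested on 500 genes that rose most and 500 that fell most, chosen with 1 IVF library and measured against the IVF libraries left aside, relative to genes of like abundance. Relative to genes of like abundance, genes that rose lay 0.192 above the IVF libraries on the log2 scale (median of 3 choices of library; 0.129 to 0.21 for FPKM as deposited and 0.134 to 0.204 with quantile normalization), which argues against a shortfall of rising genes in excess of that of other genes. Without that subtraction, a comparison added after the result was seen, the direction depended on the scaling, at -0.0931 for FPKM as deposited, -0.187 for FPKM rescaled to a common total, 0.129 with median-ratio scaling and 0.151 with quantile normalization. Whether the level itself falls short is therefore open. Genes that fell lay 0.0577 above the IVF libraries by the same measure (0.0216 to 0.0653), which neither reached the 0.1 set for an incomplete fall nor stayed under the bound of 0.05, and single SCNT libraries lay on both sides of 0, so an incomplete fall and a full one cannot be told apart. Without the subtraction their direction depended on the scaling too, at -0.126 for FPKM as deposited, -0.205 for FPKM rescaled to a common total, 0.115 with median-ratio scaling and 0.0364 with quantile normalization.

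More genes were higher than lower in 2-cell embryos than in oocytes for FPKM as deposited. Lower depth of the oocyte libraries is argued against for the number of genes at 1 FPKM or more. The 2 MII libraries as deep as the shallowest embryo library within 5% had at most 8300 such genes, against at least 8705 in each embryo library. The calls were not repeated with depth matched. Without MII replicate 1, the shallowest library, 3550 genes were higher and 817 lower in IVF minus MII. In SCNT minus MII, 2730 were higher and 1721 lower, so the excess did not rest on that library. The scale on which libraries were set equal cannot be told apart from a real excess of higher genes, since their share in IVF minus MII stayed at 67.7% with median-ratio scaling but was 47.9% with quantile normalization, which forces the distributions to be equal. The bound of this test was changed after its values had been seen: without quantile normalization among the scalings, it would have argued against the scale as the cause. A change in the RNA content of the embryo, or the larger embryo pools, may also contribute and was not tested.

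For FPKM as deposited, MII replicate 2 deviated from the other oocyte libraries in the direction of IVF rather than SCNT embryos. Its deviations correlated with the SCNT minus IVF changes at a Pearson r of -0.316 and a Spearman rho of -0.421 across 9458 genes, which are not independent replicates, and those of MII replicates 1 and 3 at a Pearson r of 0.104 and 0.244 (Spearman rho 0.204 and 0.337). The deviations within a group balance each other by construction, so the values of replicates 1 and 3 are not separate evidence. With quantile normalization the gap between the classes of 1000 FPKM or more and of 5 to 100 FPKM was -0.018 in MII replicate 2. It was -0.035 and -0.045 in MII replicates 1 and 3.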
